A study of Mus musculus with 6 samples.

How the data were processed

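RNA sequencing was done on F4/80 and CD11b sorted macrophages from white adipose tissue of mice, 3 libraries labelled HFD and 3 labelled HFD+MGIG. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made from 10 ng of RNA with a SMART-Seq v4 ultra low input kit, which amplifies cDNA before sequencing. The labels name no batch, no sex and no age, and state no strand for the counts. The sort is named in the series' design text, while the labels' protocol speaks of RNA from the tissue.

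The authors deposited a table of estimated counts per gene, which need not be whole: 33.3% to 41.8% of the detected genes per library had a fractional value. Per the submitters' processing notes, fastp, HISAT2 and StringTie and the mouse build mm10 were used; their versions and the program that made the counts are not given in the sources used here. The table held 57180 Ensembl mouse gene IDs, all of which name a gene. Symbols, gene types, exon lengths and positions came from GENCODE M21 (mm10), which held 51884 of the IDs; the other 5296 had no entry there and were tested without a symbol. The estimated counts were rounded to whole numbers, and 0 columns of the table were left unused. Total counts ranged from 14437605 to 16740417 in HFD and from 2214456 to 4904302 in HFD+MGIG, so 1 count was worth more CPM in HFD+MGIG. CPM values were scaled by the total count of the library, and fold changes by the TMM factors of the fit. Errors shown as ± are SDs over the 3 libraries of a group.

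The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3; robust fit, group as the only term, TMM factors, filterByExpr by group) on all 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with at least 5 tested members, adjusted over the lists. Camera with an estimated correlation and limma's fry were run beside it. Fry tests whether a list's genes move, on balance, in 1 direction, and does not compare the list with other genes. Camera does, and over all filtered genes those include many pseudogenes and other non-coding genes higher in HFD+MGIG. Lower camera calls in that fit can therefore arise for most lists of protein-coding genes. These tests, the filter, the 50 gene lists, the rule for naming genes and the alternatives listed next were chosen before the data were examined. These were DESeq2's size factors (RLE) or library totals in place of TMM, no filter, a minimum of 5 CPM in 3 libraries, DESeq2 1.42.0, limma voom with sample quality weights, the replicate number as a block, and each library left out in turn.

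The rule for naming genes took, in each direction, the 12 largest fold changes among genes past the threshold with at least 10 CPM in the higher group, groups that do not overlap and a proper symbol. It also took 13 genes of the catecholamine question, macrophage states and the sort, and up to 4 members with the smallest p from each list that was called or had a member past the threshold. The text names a part of these genes, picked after their values were seen. Plvap and Pecam1 were added after their values were seen, as the most abundant endothelial markers.

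The background measures were added after the data were seen. Silent families were genes with the symbols Olfr, Vmn1r, Vmn2r, Tas2r, Krtap and Defb. A gene's background bound was the 90th percentile of silent-family counts per kb in a library times the gene's exon length. The background-limited set holds protein-coding genes outside these families with at least 2 exon blocks and a mean bound of at most 0.25 of the mean CPM over all 6 libraries. It was fitted with TMM factors of its own, and the rule for naming genes was applied to it as well. An earlier definition, with at least 1 CPM and a median background of at most 0.1 in each library, was tried before it and set aside because a minimum in every library removes genes that fell. The set was refitted with the median or 90th percentile background subtracted, and with each library's trend on GC content and transcript length removed (splines with 4 degrees of freedom on each). The trend was fitted by robust regression; least squares had been run earlier and left a GC trend of the opposite sign, with Spearman's rho of the log2 fold change with GC across genes at 0.186 after and −0.192 before, against 0.0163 with robust regression. Genes are not independent replicates, so no p is given for these.

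The edgeR fits were tested on simulated counts with 200 changed genes. Both groups were drawn from the HFD proportions, without added reads on silent families. The false calls given here therefore do not cover calls that such reads would cause. Trend removal was tried on counts with a GC trend put in, while the background bound and its subtraction were not simulated. In counts simulated for 15179 of the filtered genes at the observed spread (common biological coefficient of variation 0.367), edgeR recovered 14% of genes changed 2-fold and 65% of those changed 4-fold, with 5 false among 84 calls. For 2600 background-limited genes (0.188) it recovered 94% and 100%, with 9 false among 203 calls. Within each group, pairs of libraries had a chi-square per degree of freedom of 7.05 to 34.4, which amplified libraries of 1 sample could also give; the 6 libraries were counted as separate samples, as the labels list them. Genes with exons overlapping another gene's are uncertain where the counting could have split or shared reads, and counts of multigene families are uncertain for the same reason.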

Results

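Gene expression was measured by RNA sequencing in adipose tissue macrophages, selected by the surface proteins F4/80 and CD11b, from white adipose tissue of mice on a high-fat diet (HFD). The mice were kept without or with magnesium isoglycyrrhizinate (MGIG), the magnesium salt of isoglycyrrhizic acid. There were 3 HFD and 3 HFD+MGIG libraries. Total counts were 16740417, 14437605 and 16098470 in HFD 1, 2 and 3, and 4149819, 2214456 and 4904302 in HFD+MGIG 1, 2 and 3. The series title places the study in immune and neural control of catecholamines and lipid breakdown, so the comparison asks which macrophage genes differed with MGIG. The labels do not say that each library came from a separate animal, so the p-values below measure only the spread between these libraries, which may be technical.

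Endothelial markers and genes of the extracellular matrix were lower in the HFD+MGIG libraries. Of 21 endothelial markers, 20 were lower, and of 31 genes of the extracellular matrix and the TGF-beta response, 23 were lower. Cdh5, the adherens junction cadherin of endothelial cells, had 98.9 ± 10.6 CPM (counts scaled to the library total; mean ± SD, n = 3) in HFD and 21 ± 7.53 CPM in HFD+MGIG, and Col3a1, a fibrillar collagen, had 1236 ± 251 and 221 ± 105 CPM. Of 15 macrophage identity markers, all 15 had a log2 fold change below 0 and 0 passed the threshold in edgeR's quasi-likelihood test in either direction, 2 had an unadjusted p under 0.05, and DESeq2 and limma voom called 4 and 5. Adgre1, which encodes F4/80, had 515 ± 41.2 CPM in HFD and 283 ± 132 CPM in HFD+MGIG (log2 fold change −1.13, SE 0.517, edgeR adjusted p = 0.0734), and Itgam, which encodes CD11b, had 245 ± 62.3 and 117 ± 68.4 CPM (−1.32, SE 0.554, edgeR adjusted p = 0.0545). Both were called lower by DESeq2 (adjusted p = 0.0229 and 0.0319) and limma voom (adjusted p = 0.00299 and 0.00387). In edgeR they were called without HFD+MGIG 1 (0.0403 and 0.0288) or HFD+MGIG 2 (0.007 and 0.0062). Itgam was also called without HFD 1 (0.0486) and with no filter (0.0156). In the fit over genes with little background on average described below, Adgre1 and Itgam had −0.25 and −0.48 (edgeR adjusted p = 0.411 and 0.355).

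The HFD+MGIG libraries also held more counts on gene families taken here as largely silent in macrophages. Olfactory, vomeronasal and bitter taste receptor genes, keratin-associated protein genes and beta-defensin genes, 1596 genes in all and called the silent families here, took 0.0624%, 0.280% and 0.117% of counts in HFD 1, 2 and 3 and 2.93%, 6.42% and 3.14% in HFD+MGIG 1, 2 and 3. The group means were 0.153% ± 0.113 and 4.17% ± 1.96 (SD, n = 3), a ratio of 27.2 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). Protein-coding genes held 95.4% ± 0.564 of HFD and 74.7% ± 10.8 of HFD+MGIG counts. The mitochondrially encoded genes held 3.02% ± 0.447 and 1.70% ± 0.341, and 7 of 12 were lower and 0 higher (median log2 fold change −1.22, camera adjusted p = 7.16e-05; adjusted p = 0.487 with an estimated correlation). HFD+MGIG 2 stood apart, with a Pearson correlation of log2 CPM of 0.485 to 0.565 with the HFD libraries, against 0.756 to 0.841 for HFD+MGIG 1 and 3. With every library thinned to 2214456 counts, 19556 to 21820 genes were detected in HFD and 31790 to 37213 in HFD+MGIG. The groups did not overlap in any of these measures, so library composition and treatment are confounded. Each gene's level was set beside a background bound, the 90th percentile of silent-family counts per kb in that library multiplied by the gene's exon length.

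**Figure D1:**
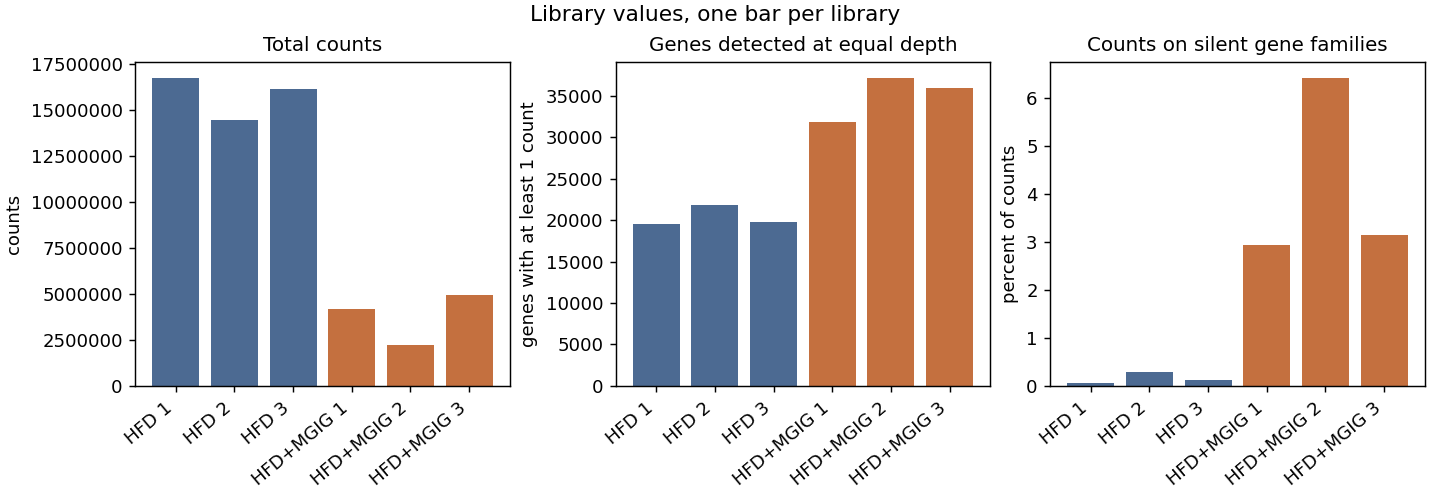
Total counts, genes with at least 1 count after thinning to equal depth, and the percentage of counts on silent gene families, with 1 bar per library. The HFD+MGIG libraries had 4149819, 2214456 and 4904302 counts and 2.93% to 6.42% of counts on the silent families, against at most 0.280% in HFD.

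Across the 23055 genes that passed the low-count filter, 14015 differed between the groups in edgeR's test at an adjusted p under 0.05, 9902 higher and 4113 lower with MGIG. The genes on each side were of different kinds. The higher genes comprised 3170 protein-coding genes outside the silent families, 1066 of the 1070 silent-family genes tested and 1204 pseudogenes. A further 4005 were other non-coding genes and 457 were genes without an entry in the annotation used. For 7908 of the 9445 higher genes with a bound, the HFD+MGIG mean was at or below it. Gpr179, a receptor gene known from the retina, and Olfr281, an olfactory receptor gene, were at 0 counts in every HFD library and at 13.1 ± 7.74 and 11.5 ± 5.57 CPM in HFD+MGIG, below their bounds of 61.1 and 29.1 CPM. The lower genes comprised 4050 protein-coding genes outside the silent families. The count of lower genes was 2551 without HFD 2, 2136 without HFD 3 and 2122 without HFD+MGIG 3. With the log2 share of silent-family counts as a covariate, edgeR called 0 genes, with 546 at an unadjusted p under 0.05.

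A set of genes with little background on average over the 6 libraries was also fitted on a scale of its own, a step added after the data were seen. These 2604 background-limited genes are protein-coding, have at least 2 exon blocks, and have a bound of at most 0.25 of their mean level over the 6 libraries. A gene high in HFD can meet this rule with an HFD+MGIG mean below its bound, as Cdh5 and Tie1 did. Their median log2 fold change was −0.91 in the fit over all filtered genes, and values in that fit can be read against it. On their own scale 280 genes differed in edgeR's test, 117 higher and 163 lower with MGIG. The fit over all filtered genes, whose scale lies lower for this set, called 1121 of the 2604 genes lower and 55 higher. Its calls included 163 of the 163 lower and 53 of the 117 higher genes in the same direction. Most of its lower calls in the set were thus not made on the set's own scale. Counts of lower list members in that fit can be read against 1121 of 2604. The direction differed between the fits for 1314 of the 2604 genes. Leaving out HFD 1, 2 or 3 gave 66, 74 or 109 genes, and leaving out HFD+MGIG 3 gave 183. Subtracting the full bound from the counts gave 0 genes in edgeR's test, with 385 at an unadjusted p under 0.05.

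Endothelial markers had the lowest median log2 fold change of the 50 gene lists, −1.86 over 21 genes, 20 of them lower and 0 higher, with 20 lower when adjusted over the list alone. Robo4, a guidance receptor of endothelium, had 106 ± 4.32 and 19.8 ± 10.2 CPM, Tie1, an angiopoietin receptor family member, had 118 ± 14.7 and 23.2 ± 12.3 CPM, and Vwf, von Willebrand factor, had 221 ± 49 and 59.5 ± 3.93 CPM in HFD and HFD+MGIG. In limma's camera test the list was lower (adjusted p = 2.22e-08), but not with an estimated correlation (adjusted p = 0.487). Camera sets a list against the other tested genes, and in this fit it called 40 of 50 lists lower and 0 higher. Among the background-limited genes 9 of 13 endothelial markers were lower and 0 higher, with 10 lower when adjusted over the list alone and a median of −1.07 (camera adjusted p = 7.97e-09; adjusted p = 0.67 with an estimated correlation). Cdh5 (ENSMUSG00000031871; mm10 chromosome 8, 104101625 to 104144511) had a log2 fold change of −2.51 (SE 0.39, edgeR adjusted p = 0.000253) over all filtered genes and −1.56 (SE 0.176, edgeR adjusted p = 0.00582) on the background-limited scale. Tie1 and Ptprb, an endothelial receptor phosphatase, had −1.69 (SE 0.217) and −1.40 (SE 0.168) on that scale, with edgeR adjusted p = 0.00685 and 0.00582, and −2.60 and −2.34 over all filtered genes. The call of Tie1 was lost with the median background subtracted (−2.15, edgeR adjusted p = 0.0689). In HFD+MGIG the means of Cdh5, Tie1, Robo4 and Vwf were below their background bounds of 26.9, 31.5, 34 and 103 CPM.

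Matrix genes followed, with a median log2 fold change of −1.49 over 31 genes, 23 lower and 0 higher (24 lower adjusted over the list alone; camera adjusted p = 9.54e-09; adjusted p = 0.487 with an estimated correlation). Among the background-limited genes 9 of 16 were lower and 0 higher (10 lower adjusted over the list alone), with a median of −0.74 (camera adjusted p = 2.89e-06; adjusted p = 0.67 with an estimated correlation). Col3a1 (ENSMUSG00000026043; mm10 chromosome 1, 45311538 to 45349706) had a log2 fold change of −2.74 (SE 0.574, edgeR adjusted p = 0.00139), and −1.87 (SE 0.216, edgeR adjusted p = 0.00582) on the background-limited scale. On that scale Col1a1, a fibrillar collagen, had −1.70 (SE 0.239) and Thbs1, the matrix glycoprotein thrombospondin, had −1.49 (SE 0.199), with edgeR adjusted p = 0.0071 and 0.00685, and over all filtered genes they had −2.59 and −2.36. Col4a1, a basement membrane collagen, had −1.76 (SE 0.194, edgeR adjusted p = 0.00582) there and −2.70 over all filtered genes, and its exons overlap those of Col4a2 on the opposite strand, so reads of the pair cannot be told apart without stranded counts. Of the 23 fibroblast markers 12 were lower and 0 higher, with a median of −1.08 (camera adjusted p = 1.79e-05; adjusted p = 0.487 with an estimated correlation). That median lay at −0.17 relative to the median of the background-limited genes. Among the background-limited genes 4 of 14 were lower, all collagen genes (4 lower and 2 higher adjusted over the list alone, 7 called by DESeq2), and the median was 0.16 with a mean of −0.063 (camera adjusted p = 0.731).

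Pericyte and adipocyte markers were lower over all filtered genes. Of 14 pericyte and smooth muscle markers 10 were lower, with a median log2 fold change of −1.42 (camera adjusted p = 0.000117; adjusted p = 0.487 with an estimated correlation). Myh11, smooth muscle myosin, had 346 ± 38.1 and 97.2 ± 51.5 CPM in HFD and HFD+MGIG (−2.08, edgeR adjusted p = 0.00509). Among the background-limited genes Myh11 had −1.22 (SE 0.226, edgeR adjusted p = 0.0137), a call lost without HFD 1 (0.0603) or HFD 2 (0.0539) and with the median background subtracted (0.0537). Of 21 adipocyte markers 14 were lower and 1 higher, with a median of −1.40 (camera adjusted p = 4.99e-06; adjusted p = 0.487 with an estimated correlation). Adipoq, the adipocyte hormone adiponectin, had 68.6 ± 28.6 and 20.6 ± 5.87 CPM, and Car3, a carbonic anhydrase abundant in fat, had 832 ± 312 and 219 ± 50 CPM (−1.99 and −2.20, edgeR adjusted p = 0.00108 and 0.00228). Of 8 adipocyte markers on the background-limited scale, Car3 alone passed the threshold in edgeR, with 4 lower when adjusted over the list alone and 4 called by DESeq2 (−1.20, SE 0.304, edgeR adjusted p = 0.0424; 0.0922 to 0.133 without HFD 1, HFD 3, HFD+MGIG 1 or HFD+MGIG 3, and 0.0822 with the median background subtracted), and Adipoq had −1.06 (SE 0.332, edgeR adjusted p = 0.082; 0.0262 without HFD 2; DESeq2 adjusted p = 0.0128). The adipocyte list was lower there (median −0.74, camera adjusted p = 0.0297), but not with an estimated correlation (adjusted p = 0.884) or with GC content and length trends removed (camera adjusted p = 0.108). Of 12 alternative settings of this fit, camera called the list in 4, with a highest adjusted p of 0.199.

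**Figure D2:**
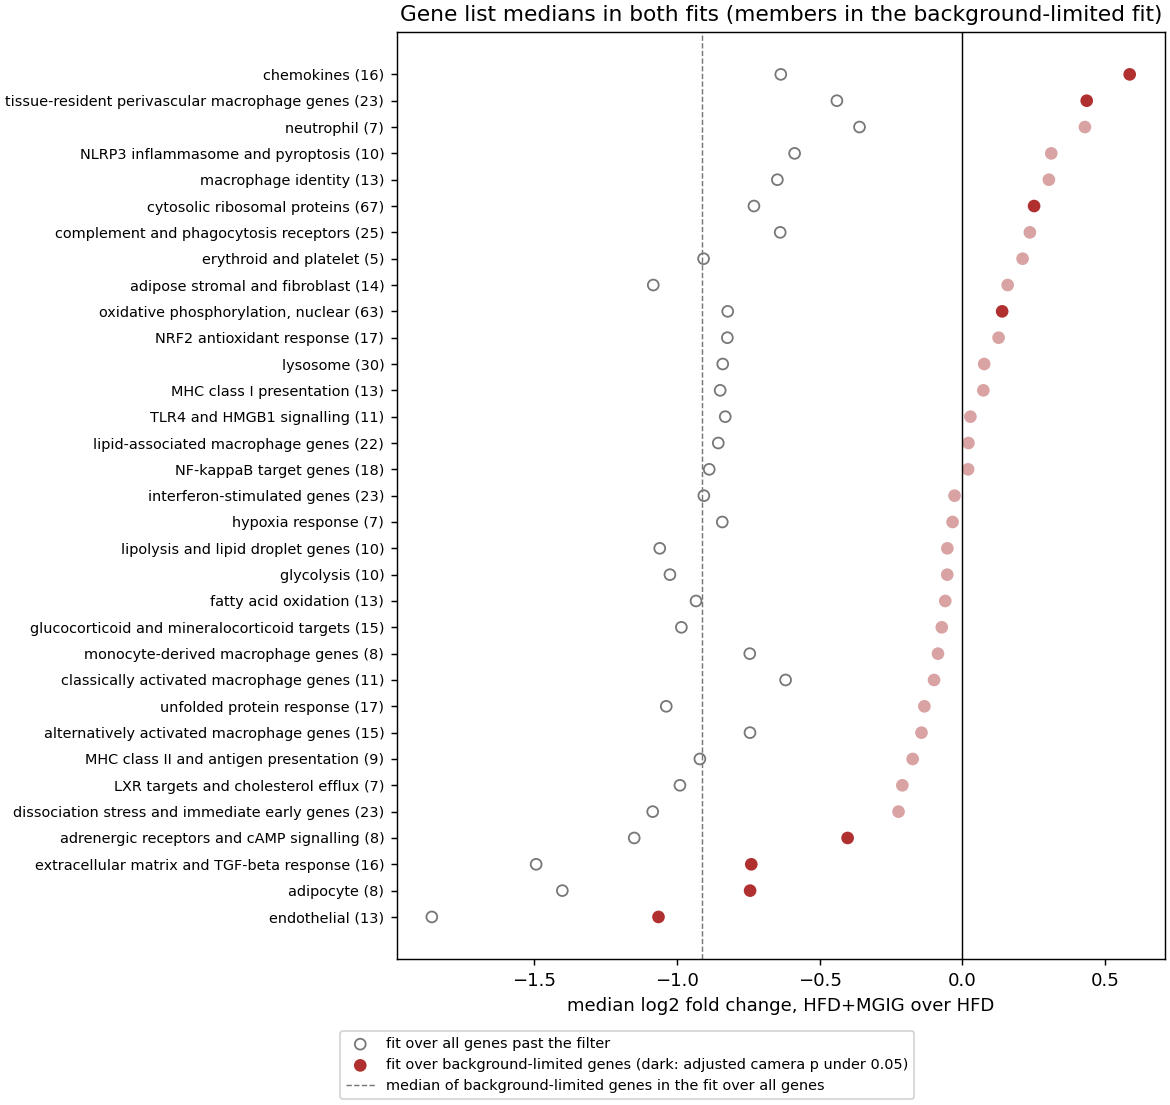
Median log2 fold change of HFD+MGIG over HFD for each gene list with at least 5 members in the background-limited set. Open circles show the fit over all filtered genes and filled circles the fit over background-limited genes, and the dashed line marks −0.91, the median of the background-limited genes in the fit over all filtered genes. Endothelial markers lie lowest on both scales, at −1.86 and −1.07.

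Keratin genes were among the 12 largest decreases of genes with at least 10 CPM in the higher group. Krt15 and Krt5, keratins of basal epidermis, had 41.1 ± 37.2 and 13.7 ± 10.3 CPM in HFD and 0.392 ± 0.365 and 0.389 ± 0.508 CPM in HFD+MGIG (log2 fold changes −7.02 and −5.16, SE 0.838 and 0.802, edgeR adjusted p = 7.35e-05 and 0.000252). Krt14 and Krt10 had 43.8 ± 34.7 and 43.3 ± 47.8 CPM in HFD and 3.03 ± 2.6 and 3.12 ± 1.47 CPM in HFD+MGIG. For these 4 genes the highest HFD level was in HFD 1, for Krt10 98.3 CPM against 20.3 and 11.3 CPM in HFD 2 and 3. Without HFD+MGIG 2 the calls of Krt14 and Krt10 were lost (edgeR adjusted p = 0.071 and 0.102). Of 11 tested mammary and other epithelial markers, a list that holds Krt14 and Krt5, 5 were higher and 2 lower, with a median log2 fold change of 1.11 (camera adjusted p = 0.826). Fscn1, an actin-bundling protein high in mature dendritic cells, had 31.7 ± 9.04 and 4.59 ± 1.49 CPM (−3.07, SE 0.353, edgeR adjusted p = 6.52e-05).

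Over all filtered genes, those of catecholamine handling showed no common direction, and most of them could not be tested on the background-limited scale. Of 16 tested genes of catecholamine breakdown and uptake, 6 were higher and 2 lower (also 6 and 2 adjusted over the list alone), with a median log2 fold change of −0.55 and a mean of 0.50 (camera adjusted p = 0.290). The background-limited set held 4 of the 19 genes of this list, 0 higher and 1 lower, with a median of 0.18. It held 1 of 12 genes of catecholamine synthesis, and both lists were too short there for camera. Maoa (ENSMUSG00000025037; mm10 chromosome X, 16619698 to 16687818), which encodes the mitochondrial enzyme that deaminates noradrenaline, had 48.8 ± 5.41 CPM in HFD and 42.8 ± 14.4 CPM in HFD+MGIG (−0.47, SE 0.356, edgeR adjusted p = 0.261) against a bound of 26.7 CPM in HFD+MGIG. Slc6a2, the noradrenaline transporter, had 0.93 ± 1.11 and 6.78 ± 4.36 CPM (2.50, SE 0.843, edgeR adjusted p = 0.0226), with an HFD+MGIG bound of 40.3 CPM, and its call was lost without HFD 3, HFD+MGIG 2 or HFD+MGIG 3 (edgeR adjusted p = 0.067, 0.0624 and 0.0779). Aldh2, mitochondrial aldehyde dehydrogenase, had 209 ± 11 and 89.6 ± 35.7 CPM, with a log2 fold change of −1.49 (edgeR adjusted p = 0.0119; 0.0559 without HFD+MGIG 3) over all filtered genes and −0.57 (SE 0.134, edgeR adjusted p = 0.0313) on the background-limited scale. The latter call was lost without HFD 1, HFD 2, HFD 3 or HFD+MGIG 3 (edgeR adjusted p = 0.0881 to 0.0971), with the median background subtracted (0.0505) and with GC content and length trends removed from each library (−0.19, edgeR adjusted p = 0.378).

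Among 26 genes of adrenergic receptors and cAMP signalling, 15 were lower and 2 higher, also when adjusted over the list alone (median log2 fold change −1.15, camera adjusted p = 5.41e-05; adjusted p = 0.487 with an estimated correlation). On the background-limited scale 2 of 8 genes of the list were lower (4 adjusted over the list alone), Gnas, the stimulatory G protein subunit (−0.60, SE 0.129, edgeR adjusted p = 0.0219), and Nr4a1, a nuclear receptor induced by cAMP (−0.75, SE 0.184, edgeR adjusted p = 0.0352). Over all filtered genes Gnas and Nr4a1 had −1.53 and −1.63 (edgeR adjusted p = 0.0147 and 0.0195; 0.059 and 0.0633 without HFD+MGIG 3). In the background-limited fit the call of Gnas was lost without any library but HFD+MGIG 2 (edgeR adjusted p = 0.0571 to 0.0758) and with the trends removed (−0.12, edgeR adjusted p = 0.643). That of Nr4a1 was lost without HFD 1, HFD 2, HFD 3 or HFD+MGIG 3 (edgeR adjusted p = 0.0659 to 0.12), with the median background subtracted (0.052) and with trends removed by least squares (0.0687). The list was lower there too (median −0.40, camera adjusted p = 0.0136; adjusted p = 0.67 with an estimated correlation), but not with the trends removed (median −0.21, camera adjusted p = 0.41).

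Of the fixed lists of macrophage activation, 15 of 30 NF-kappaB targets were lower and 0 higher over all filtered genes. Of 23 classically activated macrophage genes 6 were lower and 4 higher, and of 24 alternatively activated macrophage genes 8 were lower and 1 higher (camera for the 3 lists, adjusted p = 1.74e-06, 0.00689 and 0.000442; adjusted p = 0.487 for each list with an estimated correlation). In that fit 1121 of the 2604 background-limited genes were lower too. Relative to the median of those genes the 3 lists lay at 0.027, 0.29 and 0.17. Among the background-limited genes 1 of 18, 2 of 11 and 1 of 15 were lower and 0, 0 and 2 higher (camera adjusted p = 0.649, 0.556 and 0.339). Adjusted over the lists alone 0, 2 and 5 were lower and 0, 0 and 2 higher, and DESeq2 called 3, 2 and 7. Of 26 genes of the NLRP3 inflammasome and pyroptosis, 4 were lower and 1 higher (0 and 1 adjusted over the list alone), with a median log2 fold change of −0.59 (camera adjusted p = 0.000353; adjusted p = 0.487 with an estimated correlation). On the background-limited scale 0 of 10 passed in edgeR's test and in DESeq2, with 4 at an unadjusted p under 0.05, and the median was 0.31 (camera adjusted p = 0.331). Nlrp3, the sensor protein, had 49.4 ± 14.9 and 34.9 ± 22.4 CPM (−0.76, SE 0.499, edgeR adjusted p = 0.196). Il1b, its cytokine product, had 139 ± 21.3 and 90.9 ± 25.9 CPM, with −0.91 (SE 0.402, edgeR adjusted p = 0.0657) over all filtered genes and 0.063 (SE 0.151, edgeR adjusted p = 0.819) on the background-limited scale. Il1b over all filtered genes was called lower by DESeq2 (adjusted p = 0.0243) and limma voom (adjusted p = 0.00487), and in edgeR without HFD+MGIG 1 (0.0417) or HFD+MGIG 2 (0.0182). Tnf had −0.51 (SE 0.451, edgeR adjusted p = 0.325) and 0.44 (SE 0.256, edgeR adjusted p = 0.32) on these scales. Mrc1, the mannose receptor, had 1106 ± 178 and 676 ± 397 CPM (−0.96 and −0.14, edgeR adjusted p = 0.175 and 0.782). It was called lower over all filtered genes by limma voom (adjusted p = 0.0308) and in edgeR without HFD+MGIG 2 (0.0445). Gdf3, Arg1 and Trem2 had 3.22 ± 0.948, 2.8 ± 1.18 and 30.1 ± 5.77 CPM in HFD and 3.03 ± 0.673, 2.65 ± 2.12 and 30.7 ± 12 CPM in HFD+MGIG, below their HFD+MGIG bounds of 15.5, 14.3 and 31.7 CPM. In edgeR none of the 3 passed (adjusted p = 0.603, 0.513 and 0.583), while limma voom called Arg1 lower (−1.49, adjusted p = 0.0171). The voom quality weights were 4.61 for HFD+MGIG 3 and 0.206 for HFD+MGIG 2, and in edgeR the Arg1 log2 fold change without HFD+MGIG 3 was −0.024.

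**Figure D3:**
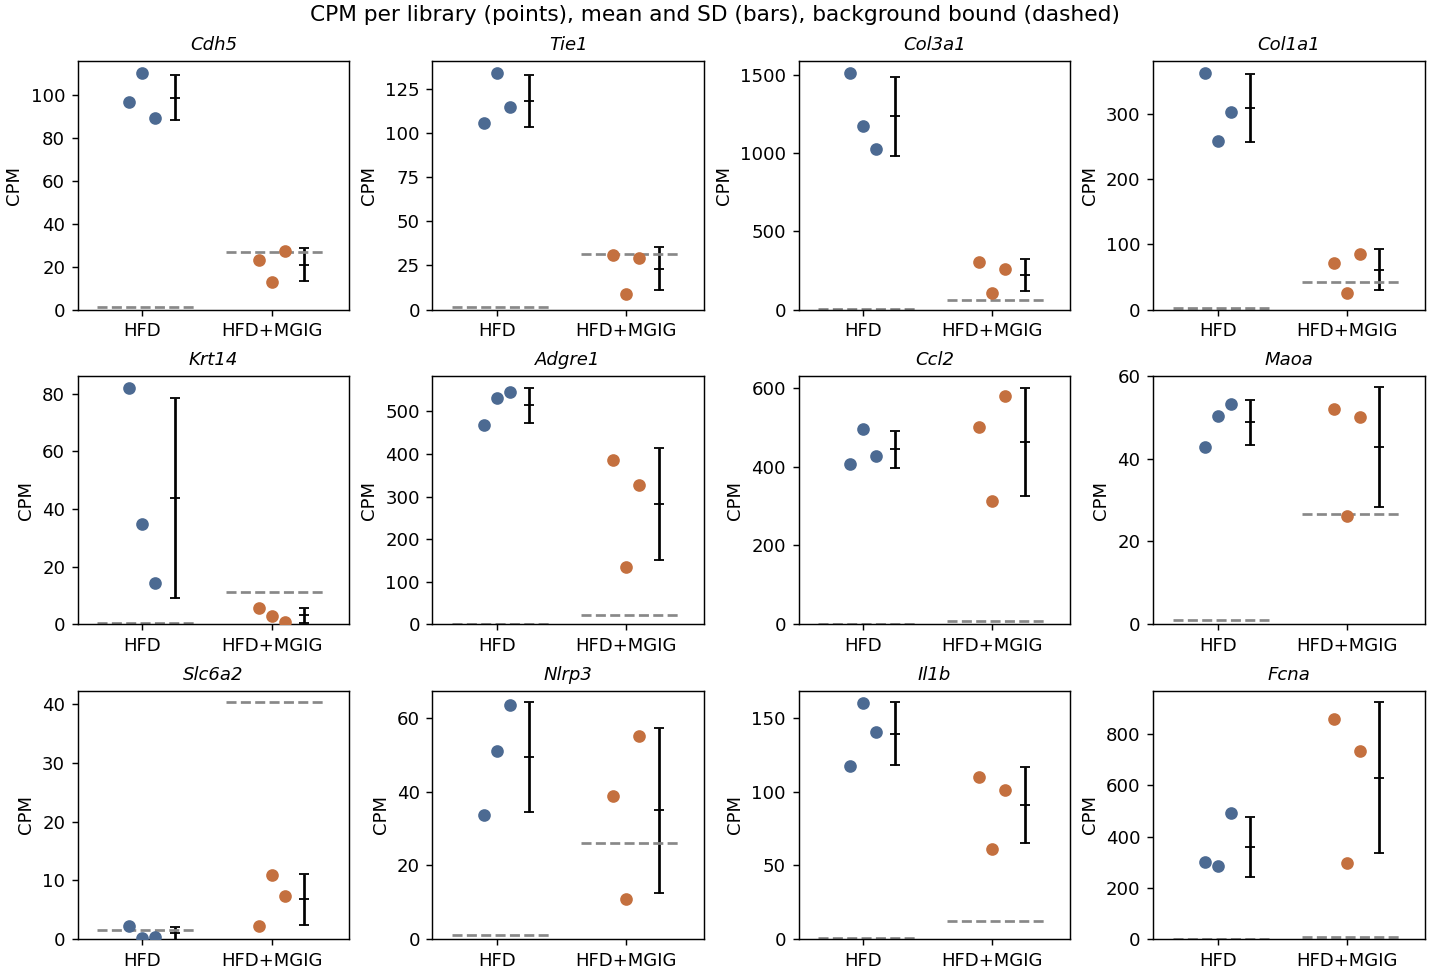
CPM of 12 genes in each library (points), with the mean and SD of the 3 libraries of each group (bars) and the mean background bound of the group (dashed lines). Cdh5, Tie1, Col3a1 and Col1a1 were lower in every HFD+MGIG library than in every HFD library, and Slc6a2 lay below its HFD+MGIG bound of 40.3 CPM.

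The medians of the macrophage identity and resident macrophage lists changed sign with the scale. The identity list had a median log2 fold change of −0.65 over all filtered genes (camera adjusted p = 0.00109; adjusted p = 0.509 with an estimated correlation), or 0.27 relative to the median of the background-limited genes. On the background-limited scale its median was 0.30 over 13 genes, 1 of them higher (camera adjusted p = 0.174). Of 26 genes of tissue-resident perivascular macrophages 2 were lower over all filtered genes (0 adjusted over the list alone), with a median of −0.44 (camera adjusted p = 0.000976; adjusted p = 0.551 with an estimated correlation). On the background-limited scale 6 of 23 were higher and 0 lower, also when adjusted over the list alone, with a median of 0.44 (camera adjusted p = 0.0136; adjusted p = 0.884 with an estimated correlation). Camera called the list in 8 of 12 alternative settings of that fit, with a highest adjusted p of 0.173. In the earlier set of 1180 genes, which is not among these settings, camera called 10 of 25 lists lower and 0 higher. Fcna, a ficolin of macrophages, had 359 ± 116 and 630.2 ± 294 CPM, with 0.55 (SE 0.537, edgeR adjusted p = 0.378) over all filtered genes and 1.43 (SE 0.252, edgeR adjusted p = 0.0131) on the background-limited scale. Colec12, a scavenger receptor, and Vsig4, a complement receptor, had 1.53 (SE 0.307) and 1.55 (SE 0.324) on that scale, with edgeR adjusted p = 0.0196 and 0.0204, and 0.39 and 0.56 over all filtered genes (edgeR adjusted p = 0.33 and 0.188). In that fit Colec12 was called higher with library totals (0.032), at least 5 CPM (0.0268) and DESeq2 (0.0157). Vsig4 was called with library totals (0.0437), at least 5 CPM (0.0487) and limma voom (0.022), and Fcna was called with limma voom (0.0282) and without HFD+MGIG 2 (0.00854). The 3 background-limited calls were lost without HFD 1 or HFD 2 (edgeR adjusted p = 0.0581 to 0.091), that of Colec12 also without HFD 3 (0.0758). That of Vsig4 was lost without HFD+MGIG 3 (log2 fold change 1.57, edgeR adjusted p = 0.0614) and with the trends removed (1.25, 0.0593).

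Chemokine genes differed in the same way between the scales. Over all filtered genes 11 of 26 were lower and 1 higher (7 and 1 adjusted over the list alone), with a median log2 fold change of −0.64 (camera adjusted p = 0.000104; adjusted p = 0.487 with an estimated correlation). On the background-limited scale 5 of 16 were higher and 0 lower (7 and 0 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 0.0109; adjusted p = 0.871 with an estimated correlation). Ccl2, the monocyte attractant, had 444 ± 46.5 and 463 ± 137 CPM, and Ccl6 had 2324 ± 179.9 and 2712 ± 925 CPM in HFD and HFD+MGIG. Their log2 fold changes were −0.23 and −0.054 over all filtered genes (edgeR adjusted p = 0.666 and 0.932), and 0.75 and 0.89 on the background-limited scale (SE 0.154 and 0.134, edgeR adjusted p = 0.0196 and 0.00958). With the trends removed, neither the list (median 0.27, camera adjusted p = 0.4) nor Ccl2 (0.28, edgeR adjusted p = 0.412) or Ccl6 (0.61, edgeR adjusted p = 0.0597) passed. The call of Ccl2 was also lost without HFD 1, HFD 2, HFD 3 or HFD+MGIG 3 (edgeR adjusted p = 0.0595 to 0.0918), and that of Ccl6 without HFD 2 (0.0539).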

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

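The tests of counts on silent gene families, at equal depth and on the X chromosome used measures defined after the data were seen, but each of these tests was set down before its own result was known. The silent families had a signal in the HFD+MGIG libraries above the level in HFD. Olfactory, vomeronasal, taste receptor, keratin-associated protein and beta-defensin genes held 4.17% of HFD+MGIG counts on average, against 0.153% in HFD.

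The HFD+MGIG libraries held fewer counts and more detected genes than the HFD libraries. Sequencing depth alone is argued against, since at equal depth the HFD+MGIG library with the fewest genes still had 1.46 times the genes of the HFD library with the most. Reads spread over the genome, from genomic DNA or from RNA other than macrophage transcripts, are a candidate explanation, as the share of silent-family counts was 27.2 times higher in HFD+MGIG, and a smaller or more degraded input amplified further may be behind it, which was not tested. Whether the reads came from the DNA of male cells or from RNA cannot be told apart: genes near 0 in HFD had 0.579 times as many HFD+MGIG counts per kb on X (385 genes) as on the autosomes (4303 genes; 95% interval 0.471 to 0.743), where 0.5 would be needed, but single autosomes ranged from 0.607 to 1.52, and outside multigene families 46 X genes gave 0.933 (0.464 to 1.43). Male cells were assumed because Ddx3y, a gene of the Y chromosome, had 61.4 to 193 CPM in the 6 libraries, and Xist had at most 4.49 CPM. The silent-family share and the number of detected genes follow the treatment library by library. An effect of MGIG on the cells or on their number therefore also stays open and was not tested.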

How the results depend on the processing

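The tests with the silent-family share as a covariate, all tests within the background-limited genes and both GC and length corrections were chosen after the result was seen, and the other tests in this part before.

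Of 14015 genes differing over all filtered genes, 9902 were higher and 4113 lower. The counts with RLE factors (14080, 10116 and 3964), DESeq2 (14951, 10285 and 4666) and the replicate number as a block (14145, 9833 and 4312) were within 1.5 times of these. Correlations of same-number deviations were 0.048 to 0.26 over all filtered genes and −0.14 to 0.2 among background-limited genes. Those of different numbers overlapped them, at −0.23 to 0.17 and −0.3 to 0.26, so pairing by that number stays open. With the block Itgam (−1.59, edgeR adjusted p = 0.0138) and Nlrp3 (−0.95, 0.0393) were called lower, and the background-limited calls of Car3 (0.0679), Gnas (0.0554), Nr4a1 (0.0523) and Aldh2 (0.0612) were lost. Without a filter 23155 genes differed, 18253 of them higher, since more genes were tested, and with at least 5 CPM in 3 libraries 6156 did, 4582 higher and 1574 lower, among fewer genes. Scaling by library totals gave 2426 lower genes and limma voom 6890. The median log2 fold change of all filtered genes was 0.38 with TMM, 0.54 with RLE and 0.74 with totals, so the scaling moves the zero point and with it the split into higher and lower genes. Leaving out 1 library gave 11781 to 17477 genes, 9645 to 12351 higher and 2122 to 5563 lower, with 2551, 2136 and 2122 lower without HFD 2, HFD 3 and HFD+MGIG 3. The silent-family share as a covariate left 0 higher and 0 lower genes in edgeR (546 at an unadjusted p under 0.05) and 2 lists; the share separates the groups, so this fit has little left to test. Among background-limited genes 280 differed, 117 higher and 163 lower, and in an earlier set of 1180 genes 550 did, 419 higher and 131 lower.

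Over all filtered genes 40 of 50 lists were lower in limma's camera test, and 32 to 44 under the other filters, scalings and libraries left out and in voom. Camera compares a list with the other tested genes, and 0 lists were higher. Those genes included silent-family genes, pseudogenes and other non-coding genes, with median log2 fold changes of 4.71, 4.74 and 3.96. The MHC class II list was called lower (camera adjusted p = 0.00147), with a median at −0.006 relative to that of the background-limited genes. A lower call in this fit therefore need not set a list apart from other expressed genes. With an estimated correlation 0 lists passed, and with fry 8. The background-limited genes gave 8 lists, 4 higher and 4 lower, and the earlier set 10, 0 higher and 10 lower.

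Within the background-limited genes, RLE factors (270), the block (212), the median background subtracted (212) and GC and length trends removed by robust regression (236) or least squares (275) gave counts within 1.5 times of 280. DESeq2 gave 416, with 188 higher. Subtracting the 90th percentile background gave 0 genes in either direction in edgeR (385 at an unadjusted p under 0.05). The log2 fold change had the same sign for 163 of the 163 lower and 115 of the 117 higher genes. This background was 0.128 to 0.421 CPM per kb in HFD and 4.58 to 9.41 in HFD+MGIG libraries. Its subtraction takes more from HFD+MGIG, so the shared sign of the lower genes is weak support for their calls. With the trends removed, 115 of the lower and 80 of the higher genes were called with and without the correction. Leaving out 1 library gave 66 to 343 genes, 12 to 154 higher and 54 to 189 lower: 66, 74, 109 and 183 without HFD 1, HFD 2, HFD 3 and HFD+MGIG 3, and 93 lower without HFD+MGIG 1. The 8 lists became 4 with robust and 3 with least-squares trend removal, 0 with an estimated correlation, 3 with fry and 3 to 9 with 1 library left out (5 without HFD 3, 3 without HFD+MGIG 3).

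For genes whose sign reversed, the cause was not tested beyond the shift of scale given above. The background-limited fit reversed Il1b (0.063), Tnf (0.44), Ccl6 (0.89) and Ccl2 (0.75). Within it Il1b reversed with the trends removed (−0.21, or −0.22 by least squares) and without HFD 1 (range −0.069 to 0.17 over libraries left out), Mrc1 with the 90th percentile background subtracted (0.15) and without HFD+MGIG 2 (−0.33 to 0.14), and Adgre1 with that background subtracted (0.084). Over all filtered genes Trem2 reversed with library totals (0.064), at least 5 CPM (0.14) and without HFD+MGIG 2 (−0.66 to 0.038); Ccl2 with totals (0.083), at least 5 CPM (0.15), voom (0.037) and without HFD+MGIG 2 (−0.38 to 0.021). Ccl6 reversed with RLE factors (0.056), totals (0.24), at least 5 CPM (0.32), DESeq2 (0.056), voom (0.096) and without HFD+MGIG 2 (−0.33 to 0.23). Of the other values of genes named in the text, over all filtered genes 636 had the same direction and side of the threshold, 30 newly passed and 9 no longer did; within the background-limited genes the numbers were 312, 2 and 96.

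Depth limits the HFD+MGIG libraries most, where 2214456 counts were the fewest, and genes at or below their background bound there cannot be read as expressed.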

Other observations

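The tests of the endothelial and matrix genes against reads spread over the genome and of the matrix genes against GC and length trends, the use of the whole fibroblast list and the spread asked of the test with the bound subtracted were chosen after the result was seen, as were the fits over background-limited genes on which the tests here rest, and the other tests were set down before their results were known.

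Themis, Syt1 and Msln, picked after their values were seen from the T cell, neuron and mesothelial lists, were higher in HFD+MGIG at levels below the background bound. Themis had 0.823 ± 0.434 and 22.7 ± 12.2 CPM in HFD and HFD+MGIG (bound 74.8), Syt1 had 0.621 ± 0.199 and 34.9 ± 17.3 CPM (bound 53.4). Msln had 0.345 ± 0.254 and 17.7 ± 12.3 CPM (bound 19.6). The lists they belong to went both ways, with 5 of 22 T cell, 4 of 16 Schwann cell and neuron and 3 of 8 mesothelial markers higher and 2, 4 and 2 lower (camera adjusted p = 0.811, 0.715 and 0.783). Zfp488 and Zscan4e, zinc finger genes, were far above their bounds of 27.6 and 11.5 CPM, at 803 ± 511 and 61.2 ± 30.1 CPM in HFD+MGIG against 18.5 ± 14.7 and 1.21 ± 0.855 CPM in HFD (log2 fold changes 6.43 and 6.55 on the background-limited scale, SE 1.04 and 0.85, edgeR adjusted p = 0.0144 and 0.0109). The call of Zfp488 was lost without HFD 1 (0.0588) or HFD 3 (0.0863), and that of Zscan4e without HFD 3 (0.0639). Both were higher over all filtered genes too (5.0 and 5.26).

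Relative to the median of the background-limited genes, the lists of fatty acid synthesis and lipolysis lay at −0.054 and −0.15 over all filtered genes. Those of cholesterol and sterol synthesis, LXR targets and cholesterol efflux, and fatty acid oxidation lay at 0.34, −0.076 and −0.019. Of 21 genes of fatty acid synthesis and desaturation 13 were lower and 2 higher (median log2 fold change −0.97, camera adjusted p = 0.000218; adjusted p = 0.487 with an estimated correlation). Of 20 genes of lipolysis and lipid droplets, 10 were lower and 1 higher (median −1.06, camera adjusted p = 2.81e-05; adjusted p = 0.487 with an estimated correlation). Scd1, a fatty acid desaturase, had 1267 ± 513 CPM in HFD and 271 ± 64.2 CPM in HFD+MGIG (−2.50, edgeR adjusted p = 0.00153), and Dgat2, an enzyme of triglyceride synthesis, had 29.5 ± 8.03 and 10.2 ± 2.51 CPM. Scd1 on the background-limited scale had −1.50 (SE 0.324, edgeR adjusted p = 0.0244), a call lost without HFD 1, HFD 3, HFD+MGIG 1 or HFD+MGIG 3 (0.0671 to 0.0918) and with the trends removed (−1.28, 0.0706). Mgll, monoglyceride lipase, had −1.86 over all filtered genes and −0.89 there (SE 0.198, edgeR adjusted p = 0.0251), lost without HFD 1, HFD 2, HFD 3 or HFD+MGIG 1 (0.0541 to 0.0922) and with the trends removed (−0.49, 0.191). The lipolysis list was not called there (median −0.053, camera adjusted p = 0.561). The fatty acid synthesis list had a median of −0.41 there over 4 genes, too few for camera, with 1 lower (2 adjusted over the list alone) and 0 higher.

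Tgm2, Hif1a and Socs3, 3 genes picked after their values were seen, were lower on both scales, while their lists were not called among the background-limited genes. There 1 of 15 alternatively activated macrophage genes was lower and 2 higher (5 and 2 adjusted over the list alone, 7 in DESeq2; camera adjusted p = 0.339), and 2 of 7 hypoxia response genes lower and 0 higher (0.556). Of the classically activated macrophage genes 2 of 11 were lower and 0 higher (0.556), and 5 of 23 dissociation stress and immediate early genes lower and 0 higher (0.0933). Tgm2, a transglutaminase of alternatively activated macrophages, had 354 ± 18.3 and 114 ± 44.7 CPM in HFD and HFD+MGIG. Hif1a, the hypoxia factor, had 372 ± 48.8 and 134 ± 45.8 CPM, and Socs3, an inhibitor of cytokine signalling, had 384 ± 58.2 and 131 ± 57.9 CPM. Over all filtered genes they had −1.91, −1.76 and −1.81 (edgeR adjusted p = 0.00438, 0.00647 and 0.00717). On the background-limited scale these 3 genes had log2 fold changes of −0.98, −0.81 and −0.91 (SE 0.136, 0.142 and 0.167, edgeR adjusted p = 0.0071, 0.0126 and 0.0133). They also passed with GC and length trends removed by robust regression (−0.56, −0.73 and −0.61), while the call of Hif1a was lost without HFD 2 (0.0581) and that of Socs3 without HFD 1 (0.0581) and with trends removed by least squares (0.0569). Subtracting the 90th percentile background ended all 3 calls (−1.12, −0.98 and −0.72, edgeR adjusted p = 0.178, 0.173 and 0.148).

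Endothelial markers and matrix genes were lower among the background-limited genes, and the 2 most abundant endothelial markers, singled out after their values were seen, were Plvap (603 ± 85.3 and 182 ± 63.8 CPM in HFD and HFD+MGIG) and Pecam1 (539 ± 25.6 and 150.4 ± 68.9 CPM). GC and length trends are argued against as the whole cause for the endothelial list, whose median log2 fold change was −0.82 with them removed (SD 0.387, camera adjusted p = 1.82e-09; 0.531 with an estimated correlation), but stay open for the matrix list (−0.59, SD 0.634, 11 of 16 below 0). Reads spread over the genome would lower a gene that received none by 0.53 if the typical background-limited gene were raised to its bound. The endothelial median without trend removal exceeds this by just over its SD (−1.07, SD 0.504), and the matrix median does not (−0.74, SD 0.71). The margin for the endothelial list is narrow under a rule set after the result was seen. Such reads are therefore not excluded for it, and they stay open for the matrix list. Fewer fibroblasts are argued against only for the markers in the set. There the 10 fibroblast markers other than collagens had a median of 0.34 (SD 0.459) and all 14, collagens included, 0.14 (SD 0.809) against −1.02 for the collagens. Over all filtered genes 12 of 23 fibroblast markers were lower and 0 higher. The markers outside the set were not part of this test, so a loss of fibroblasts is not excluded. Fewer endothelial cells carried through the F4/80 and CD11b sort, which would be expected to remove them, are a candidate explanation beside an untested effect of MGIG within macrophages. After removal of the trends 13 of 13 markers were below 0 (12 of 13 before), with a median −1.04 relative to the macrophage identity list. These came from a list of 21, of which 2 belong to another list and 0 were absent from HFD. The list was already known to be the lowest of the 50 in these data, so these values largely restate its choice. They do not tell the 2 explanations apart.

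The lists of resident macrophage and chemokine genes were shifted higher among the background-limited genes, with 6 of 23 and 5 of 16 members past the threshold, but not with an estimated correlation (camera adjusted p = 0.884 and 0.871). Cytosolic ribosomal proteins (0 of 67 higher, median 0.25, camera adjusted p = 0.000644) and nuclear oxidative phosphorylation genes (1 of 63, 0.14, 0.0418) were also called higher. With GC and length trends removed neither was (0.027 and −0.055, camera adjusted p = 0.542 and 0.4), while the lysosome list was (0.18, camera adjusted p = 0.0135). Reads spread over the genome stay open: with the background bound subtracted the medians were 0.72 for resident macrophage genes (SD 0.707, camera adjusted p = 8.75e-06) and 0.97 for chemokines (SD 0.817, camera adjusted p = 6.64e-05), above 0.2 by less than the SD, and the subtraction also shifts the scale of the set. GC and length trends stay open too: with them removed the medians were 0.28 (SD 0.546, camera adjusted p = 0.0206; 0.861 with an estimated correlation) and 0.27 (SD 0.486, camera adjusted p = 0.4), between the values that would have told for or against them. In the earlier set camera called 0 lists higher. An effect of MGIG on the macrophages, or a larger share of resident macrophages, was not tested and stays open.

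The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. In edgeR the real split gave 14015 genes over all filtered genes and 280 among the background-limited genes, the highest of the 9 others gave 0 and 0 (69 and 182 at an unadjusted p under 0.05), and 1 split, the real one, gave as many genes in each case.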
